A study of Homo sapiens with 6 samples.

How the data were processed

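The series holds 6 RNA-seq libraries of LNCaP cells, 3 with Flag-KDM4B and 3 with the empty vector, grouped by the genotype and title labels. Total RNA was extracted with Trizol and libraries were made with standard Illumina protocols, per the labels. The titles of the libraries labelled KDM4B carry a suffix that the vector titles lack, so a library batch, if there was one, cannot be told apart from the group. HISAT, StringTie and Cufflinks and the builds GRCh38 and hg38 are named in the submitters' processing notes without a role or version; the splicing caller and the annotation are not given in the sources used here.

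The authors deposited FPKM values per gene, rounded to 2 decimals, per the file headers, and 19400 of 19571 gene IDs were found in the RefSeq gene table of GRCh38, which was used for names only. The authors also deposited read counts per splicing event and library for 4 event types, as whole numbers that were not normalized. Alternative 3' splice sites were not analysed here. Each event has 1 count per library that joins both splice forms. This follows from sets of 2 SE events and 1 MXE event on the same exons: the sum of the SE counts minus the MXE count gives the skipping count multiplied by 2, and 19478 of 19482 such values (99.98%) were exactly even and not negative. From 3247 such sets, 2 of them left out, inclusion and skipping counts were recovered for 6046 SE events and exon-wise counts for 3245 MXE events. Of 295 exon flanks recovered from more than 1 set, all 295 gave the same skipping counts. The planned tests assumed counts of both forms for every event; A5SS and RI events, for which they could not be recovered, were instead tested against the summed SE counts of their gene. The MXE table has 1 row without coordinates, which no test used.

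Expression was tested with limma 3.58.1 (R 4.3.3; linear models with a mean-variance trend) on log2(FPKM + 1) for genes with a mean FPKM of at least 1, two-sided, with Benjamini-Hochberg adjustment at 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes, and genes rise or fall in the libraries labelled KDM4B relative to the vector libraries. Scaled values divide each library by its median of ratios, 0.904, 0.942 and 0.914 for the libraries labelled KDM4B and 1.09 for each vector library. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over 26 lists with at least 3 tested genes. Of the 28 lists, the mitochondrial transcripts had 0 members in the table. FPKM carry no counts, so DESeq2 was not run on genes. The value of a single read in short genes put the relative depth of the libraries between 0.983 and 1.03, from 14 to 17 genes each.

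Splice forms were tested with edgeR 4.0.16 (glmQLFit and glmQLFTest) on both forms of each library, with terms for library, form and form by group, for events with at least 10 reads in each library and at least 10 reads of each form over all libraries. SE events of a gene can share skipping counts, so calls are also given by gene. Numbers of reads in the exon grow with its length, from a median of 2.67 per FPKM for exons of 25 to 75 bases to 11.8 for 200 to 400 bases. Positions were counted from 0 at the start in the files (41.0% of exon lengths were then multiples of 3, against 29.2% otherwise) and are given from 1; 4 sequence names belong to haplotypes or unplaced sequences.

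Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom of 2.43 to 2.99 within groups and 28.7 to 34.1 between groups over 8536 events, and no library was a copy of another. On simulated data with 200 changed genes, limma recovered 88.0% of changes of 0.5 and 94.0% of changes of 1 (log2) among 12148 genes. With 200 changed events of each type, the form test recovered 10.0% and 40.0% of log2 odds ratios of 1 and 2 among 1351 SE events, 72.0% and 92.0% among 2997 MXE events, 91.0% and 96.0% among 1193 A5SS events, and 96.0% and 100% among 783 RI events. Intervals and tests on reads cover counting error and the spread between these libraries only.

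Named genes were chosen by a rule fixed before the data were examined: 12 genes whatever they showed, the 10 largest rises and 10 largest falls without overlap of the groups, and up to 4 members of each list with the lowest p. Named events were the 5 largest changes in each direction per type with at least 20 reads in each library and no overlap of the groups, all tested KDM4B events, and events of prostate cancer splicing genes that changed by at least 10 percentage points. Genes on the Y chromosome and XIST were left out, and some of the fixed genes, events and lists are not reported here. The gene lists, the tests and the alternatives were also fixed before the data were examined, except where stated. Alternatives were another pseudocount, filter, scaling, variance model and test, a replicate block, and each library left out in turn, with DESeq2 1.42.0 for the splice forms. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.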

Results

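RNA was sequenced from LNCaP cells, an androgen-sensitive human prostate cancer cell line, that stably carried either Flag-tagged KDM4B, a histone lysine demethylase, or the empty vector. There were 3 libraries labelled KDM4B (replicates 1, 2 and 4) and 3 vector libraries (replicates 1, 2 and 3), all from cells kept for 3 days before harvest in medium with 10% of a serum that the labels abbreviate as CFBS. The deposited tables held FPKM values of 19571 genes and read counts of 40622 skipped exon (SE), 9290 mutually exclusive exon (MXE), 1359 alternative 5' splice site (A5SS) and 869 retained intron (RI) events. SE counts summed to between 14212396 and 14787321 in the libraries labelled KDM4B and to between 16451082 and 17021204 in the vector libraries; these are sums over events that share reads, not library depths. The labels do not say that the replicates were separate cultures, so every p-value measures only the spread between these samples, which may be technical.

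The first question was whether the label was visible in the KDM4B transcript itself. KDM4B (gene 23030) measured 26.4 ± 0.71 FPKM (SD, n = 3) in the libraries labelled KDM4B and 25.1 ± 0.29 FPKM (SD, n = 3) in the vector libraries, a log2 fold change of 0.07 (SE 0.039) that missed the threshold (limma, adjusted p = 0.113). After median-of-ratios scaling the difference was 0.31 (SE 0.034) and passed it (adjusted p = 1.93e-05), as did 0.36 in the edgeR test on its most-read SE event (adjusted p = 0.000411). Neither value amounts to a 2-fold difference, so the libraries are called "labelled KDM4B" throughout and every direction below rests on that label. Of the related demethylases, KDM4A (9682) fell by 0.14 on the log2 scale as deposited but stood at 0.10 after scaling. Its call as deposited was lost without KDM4B replicate 1 or vector replicate 1 (limma, adjusted p = 0.0657 and 0.0678) and with a replicate block (0.0567). KDM4C (23081) fell by 0.25 (adjusted p = 0.0013), a call that was lost after scaling (log2 fold change -0.03). KDM4D was under the expression filter, at 0.90, 0.70 and 0.85 FPKM in the libraries labelled KDM4B and 1.09, 0.82 and 0.95 FPKM in the vector libraries.

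Most of the 10 largest rises in the libraries labelled KDM4B were RNAs that do not carry a poly(A) tail. RNA28S5 measured 22459 ± 2522 FPKM in the libraries labelled KDM4B and 547 ± 318 FPKM in the vector libraries (SD, n = 3 each), RN7SK 149 ± 28.7 against 7.52 ± 7.19 FPKM and RPPH1, the RNA of RNase P, 33.9 ± 4.63 against 1.18 ± 0.69 FPKM. SNORD3A (22.9 against 1.65 FPKM) and RNA5S16 (8.52 against 0.16 FPKM) were also among the 10 largest rises, with RNA18S5, RNA45S5, RNA5-8S5 and the protein-coding LRRN1 and DDC. Ribosomal RNA genes took 9.58% ± 1.28 of the FPKM sum in the libraries labelled KDM4B and 0.25% ± 0.19 in the vector libraries. Vector replicate 1 stood apart from the other vector libraries, with 0.47% ribosomal RNA and 15.8 FPKM of RN7SK. Without it the vector means were 0.15% for the ribosomal RNA share and, in FPKM, 363 for RNA28S5, 3.38 for RN7SK, 0.785 for RPPH1 and 0.055 for RNA5S16, so the differences from the libraries labelled KDM4B were larger. Near-identical copies of these genes share reads, so the value of a single copy is uncertain. Every gene group below was compared between libraries that differed in this share.

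**Figure D1:**
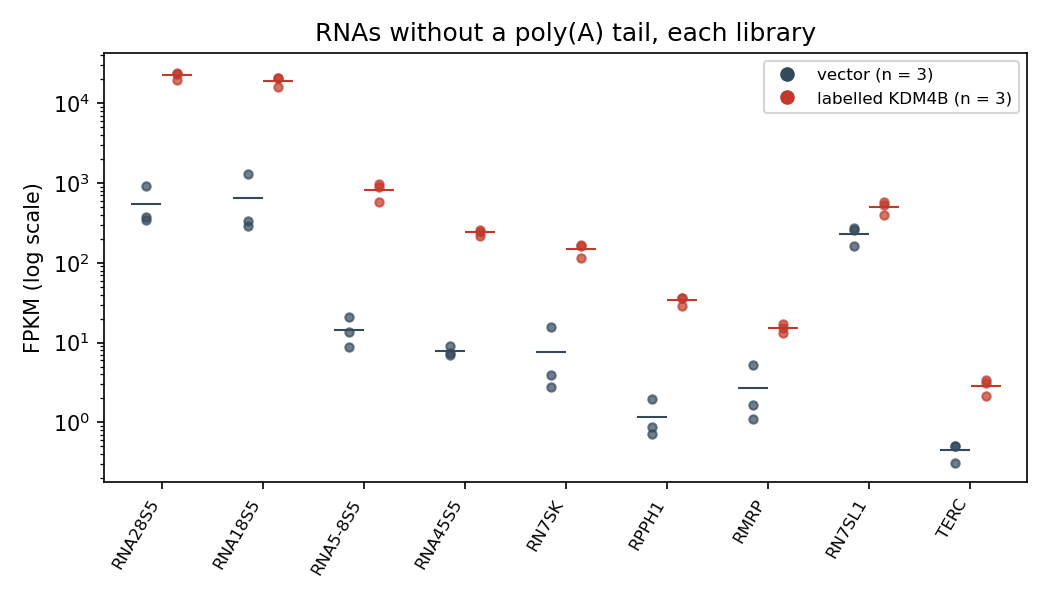
FPKM on a log axis of 9 structural RNAs, with 1 point per library and a bar at the mean of 3 libraries, in vector libraries and libraries labelled KDM4B. RNA28S5 averages 22459 FPKM in the libraries labelled KDM4B and 547 FPKM in the vector libraries.

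Of the fixed gene lists, the androgen-induced genes had the lowest median change. KLK3, which encodes prostate-specific antigen, measured 441 ± 41.2 FPKM in the libraries labelled KDM4B and 2212 ± 49.4 FPKM in the vector libraries (SD, n = 3 each; log2 fold change -2.33, SE 0.056; limma, adjusted p = 6.19e-11). KLK2 fell from 168 to 20.8 FPKM, TMPRSS2 from 421 to 76.7 FPKM, and FKBP5 from 75.9 to 17.0 FPKM. Of 44 androgen-induced genes tested, 42 fell and 2 rose, with the same counts adjusted over the list alone, and their median log2 fold change was -1.39 (-1.14 after scaling, with 38 falls and 3 rises). Of 11 androgen-repressed genes, 10 rose and 1 fell, again with the same counts adjusted over the list alone, with a median of 1.54 (1.68 after scaling). The rises included DDC (dopa decarboxylase; 184 against 21.2 FPKM), LRRN1 (23.3 against 1.90 FPKM), BCHE (butyrylcholinesterase; 6.68 against 0.16 FPKM) and CAMK2N1 (18.8 against 2.97 FPKM). Set tests with the preset correlation called both lists (camera, adjusted p = 8.54e-10 and 9.15e-11), and neither call held with an estimated correlation (adjusted p = 0.112 for each). These libraries also differed in ribosomal RNA, at 9.58% against 0.25% of the FPKM sum (0.15% without vector replicate 1).

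**Figure D2:**
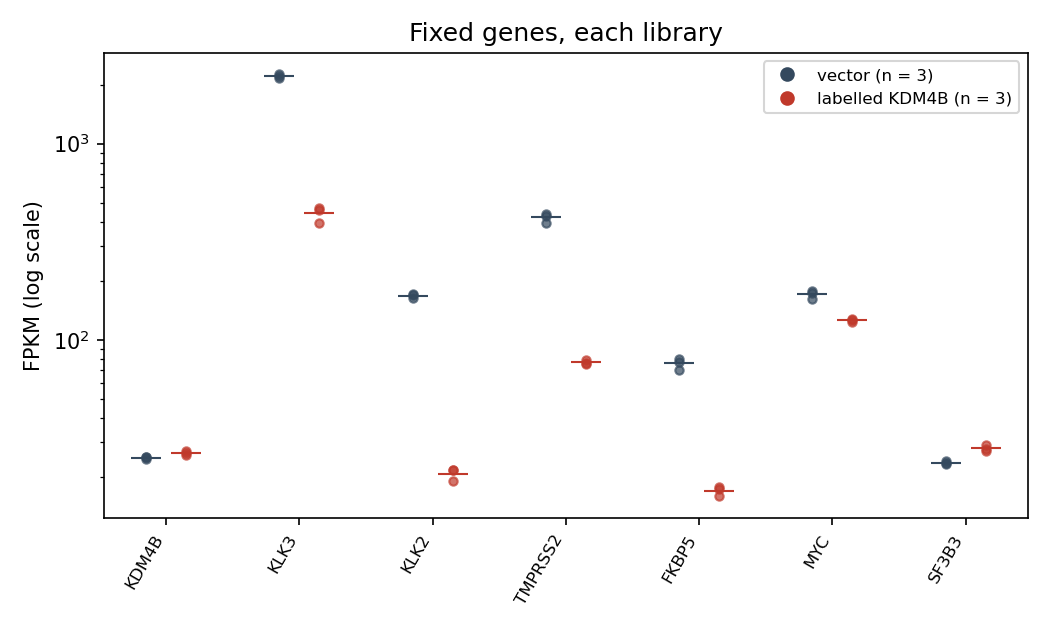
FPKM on a log axis of 7 genes fixed before the data were examined, with 1 point per library and a bar at the mean of 3 libraries, in vector libraries and libraries labelled KDM4B. KLK3, KLK2, TMPRSS2 and FKBP5 lie lower in all 3 libraries labelled KDM4B, while KDM4B lies at 26.4 against 25.1 FPKM.

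Stress genes separated in opposite directions. All 25 tested genes of the unfolded protein and amino acid stress list fell (25 adjusted over the list alone), with a median log2 fold change of -0.98 (-0.73 after scaling, again with 25 falls); TRIB3, a pseudokinase induced by this response, measured 40.1 against 289 FPKM, PCK2 64.5 against 272 FPKM, ASNS (asparagine synthetase) 59.8 against 158 FPKM and HERPUD1 65.2 against 163 FPKM. Of 13 heat shock protein genes, 10 rose and 1 fell, also when adjusted over the list alone, with a median of 0.37 (0.62 after scaling, with 13 rises); HSP90AA1 rose from 192 to 317 FPKM, DNAJA1 from 85.6 to 139 FPKM and DNAJB1 from 30.6 to 43.2 FPKM. Camera called both lists with the preset correlation (adjusted p = 3.58e-07 and 1.62e-08) and neither with an estimated correlation (adjusted p = 0.304 for each). Among 13 immediate early genes 9 fell and 1 rose, including ATF3 (13.9 against 53.3 FPKM), KLF4 (2.10 against 8.03 FPKM) and JUN (18.0 against 33.6 FPKM), with no camera call (adjusted p = 0.227); after scaling 9 fell and 4 rose.

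Across all genes, 8951 of 12148 tested differed between the groups, 1628 higher and 7323 lower in the libraries labelled KDM4B (limma on log2(FPKM + 1), Benjamini-Hochberg adjusted p below 0.05). The median log2 fold change of all tested genes was -0.22. Median-of-ratios scaling moved that median to 0.00 and the split to 4136 higher and 4114 lower, so the share of called genes that were higher went from 18.2% to 50.1%. Many falls called as deposited thus depended on the scale of the libraries and do not by themselves show regulation of the gene. Ribosomal RNA took 9.58% of the FPKM sum in the libraries labelled KDM4B and 0.25% in the vector libraries. Its part in this shift was not tested. A change of at least 2-fold was seen for 152 higher and 416 lower genes, and for 214 and 243 after scaling. In FPKM as deposited the groups did not overlap for 76.3% of tested genes, where chance gives 10% for a single gene. A shift shared by all genes can also separate the groups, and overlap after scaling was not counted. The largest falls were those of TARP (1.30 against 39.6 FPKM), SAT1 (a polyamine acetyltransferase; 26.4 against 233 FPKM), S100P (2.75 against 30.8 FPKM), ST6GALNAC1, NPPC, KLK2, SLC45A3, CHRNA2, TRIB3 and GTPBP2, with log2 fold changes between -4.16 and -2.80. TARP lies within the T-cell receptor gamma locus. How reads of overlapping genes were assigned is not given in the sources used here, so the TARP value is uncertain.

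The other fixed lists moved less or in both directions, and many of their counts followed the shift of all genes. Splicing factors fell more often than they rose as deposited and rose more often after scaling: 11 rose and 14 fell of 40 core spliceosome genes (29 and 3 after scaling), and 8 rose and 23 fell of 46 SR protein, hnRNP and other regulator genes (27 and 7 after scaling). ESRP1, an epithelial splicing regulator, fell under both (49.96 to 17.8 FPKM; log2 fold change -1.44, and -1.21 after scaling), and SFPQ rose from 71.3 to 117 FPKM (log2 fold change 0.71, and 0.95 after scaling). In the edgeR test on its most-read SE event the SFPQ call was lost (log2 fold change 0.24, adjusted p = 0.0804). SF3B3, a component of the U2 particle, rose from 23.6 ± 0.31 to 27.9 ± 0.99 FPKM (log2 fold change 0.23, SE 0.041, and 0.47 after scaling; adjusted p = 0.000313). Cytosolic ribosomal protein genes fell in 62 of 78 cases and rose in 0 as deposited, and after scaling 31 rose and 17 fell; their processed pseudogenes can share reads. Zinc finger genes fell in 281 of 429 cases and rose in 18 (140 and 69 after scaling). MYC fell from 171 to 125 FPKM (log2 fold change -0.44, and -0.20 after scaling), within a list of 30 MYC and ribosome biogenesis genes of which 8 rose and 11 fell (21 and 3 after scaling).

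Cell cycle lists showed no common direction as deposited. Of 25 mitosis genes 6 rose and 14 fell (10 and 4 after scaling) and of 30 replication genes 8 rose and 12 fell (18 and 7 after scaling). Of 24 hypoxia-induced genes 4 rose and 15 fell (8 and 10 after scaling), with VEGFA at 24.5 against 75.5 FPKM and EGLN3 at 8.30 against 2.41 FPKM. Of 28 sterol and fatty acid synthesis genes 4 rose and 11 fell (15 and 8 after scaling). Of 23 p53 targets 10 rose and 6 fell (15 and 4 after scaling), with GDF15 at 178 against 825 FPKM and BTG2 at 26.6 against 11.9 FPKM. Interferon-stimulated genes gave 3 rises and 9 falls of 21 (6 and 5 after scaling), NF-kB genes 1 rise and 2 falls of 4 (3 and 0 after scaling), and histone genes, which include near-identical copies, 12 rises and 6 falls of 39 (23 and 3 after scaling). Other histone methylation enzymes gave 5 rises and 10 falls of 25 (15 and 4 after scaling), among them a fall of EZH2 from 24.5 to 11.0 FPKM.

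Markers of cell identity also went both ways. Luminal markers rose in 7 and fell in 12 of 23 cases (10 and 11 after scaling), with SPDEF falling from 153 to 44.7 FPKM and KRT18 from 426 to 231 FPKM. Basal and mesenchymal markers rose in 4 and fell in 4 of 8 cases: FN1 (fibronectin) rose from 10.9 to 33.2 FPKM, and VIM (vimentin) fell from 3.84 to 0.48 FPKM. Neuroendocrine markers rose in 3 and fell in 3 of 7 cases (4 and 2 after scaling), with SYT4 at 319 against 146 FPKM. Cancer-testis antigen genes rose in 6 and fell in 3 of 12 cases (9 and 2 after scaling), MAGEA4 rising from 10.6 to 23.8 FPKM. Neither of the 2 tested immune and endothelial markers passed the test (1 was higher after scaling). Of the 3 tested KDM4 family genes 0 rose and 2 fell (2 and 0 after scaling). Genes with known splice variants in prostate cancer rose in 13 and fell in 26 of 49 cases (24 and 16 after scaling). Adjusted over the list alone, the counts of these lists were the same as over all genes except for 17 rises and 280 falls of zinc finger genes, 64 falls of ribosomal protein genes, 14 falls of luminal markers and 10 rises of histone genes.

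With the preset correlation camera called 12 of 26 lists relative to other genes. The androgen-induced and stress lists were called lower, and 10 lists higher: among them the androgen-repressed, heat shock, replication, core spliceosome, MYC, p53, neuroendocrine, cancer-testis and histone lists. The replication, core spliceosome and MYC lists were called higher although their medians were -0.01, -0.03 and -0.06, since other genes lay lower, and the p53 list had a median of 0.03 and a mean of -0.0066. With an estimated correlation camera called 0 of 26 lists (3 at an unadjusted p below 0.05; adjusted p = 0.112 to 0.803 for the 12 lists), while fry, which does not compare a list with other genes, called 20.

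**Figure D3:**
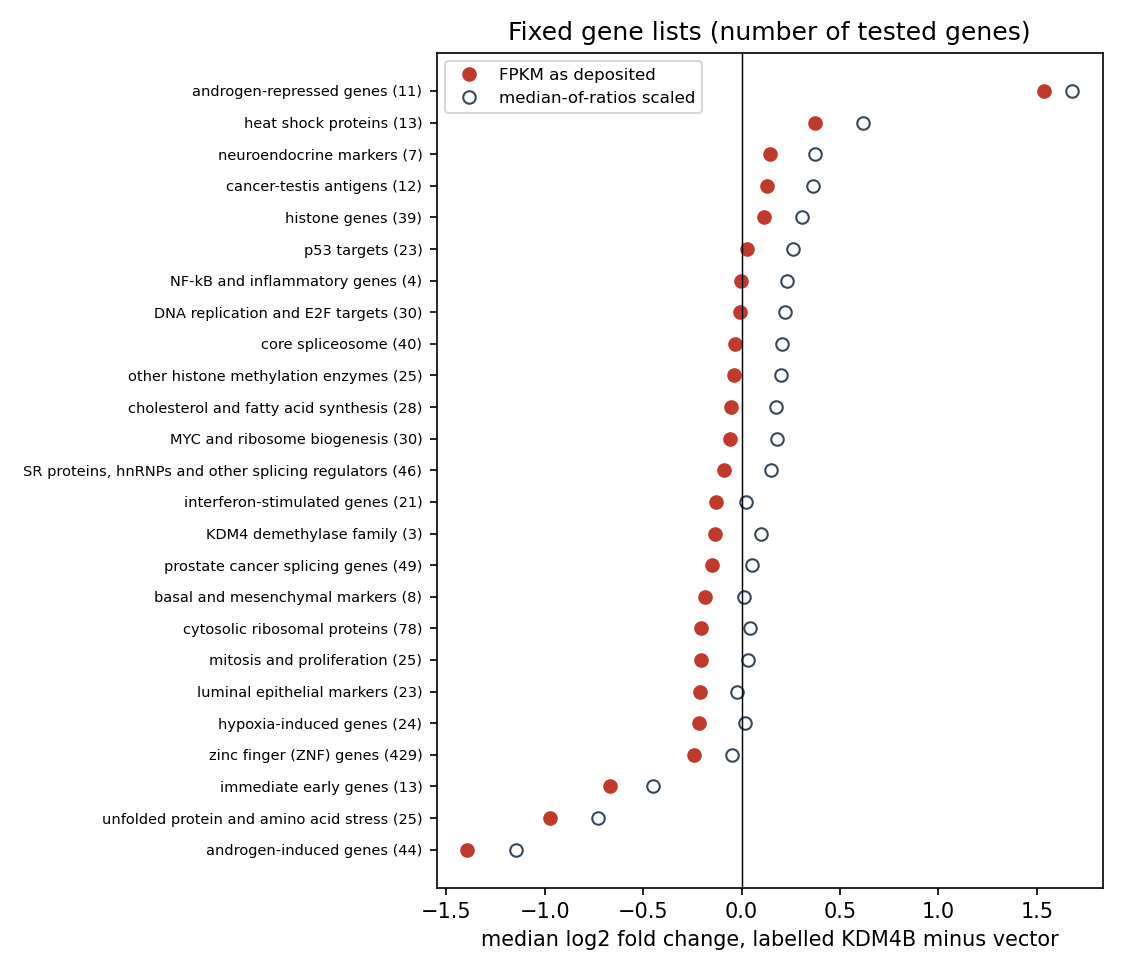
Median log2 fold change, libraries labelled KDM4B minus vector libraries, of 25 fixed gene lists with at least 3 tested genes, from FPKM as deposited (filled) and after median-of-ratios scaling (open); the number of tested genes stands in parentheses. The androgen-induced list lies at -1.39 as deposited and -1.14 after scaling.

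The series asks which alternative splicing events differ between the groups. Most SE events with a called change had a smaller share of inclusion reads in the libraries labelled KDM4B. Of 40622 deposited SE events, 6046 had recovered counts, and 1351 of these passed the read filters. Among the 1351, 64 fell and 11 rose in inclusion (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). Recovery needs 2 exons between the same flanks, so a skipping read lacks both. Reads that skip only the named exon were not counted as skipping. Over all 1351 events the directions were near even, with 53.6% below 0 and a median log2 odds ratio of -0.083 (-0.034 for those not called). The SE calls lay in 37 genes, 30 with falls only and 7 with rises only (exact binomial test, two-sided p = 0.000191). This binomial test was not among the planned tests. It treats genes of the same libraries as independent, so its p-value does not measure the spread between libraries. Inclusion is given as the share of an event's reads that belonged to the inclusion form, which is not an isoform fraction because reads within the exon are counted. A CPNE7 exon (chromosome 16, 89649852 to 89649936) had 28.0% ± 2.65 inclusion reads against 71.3% ± 14.6 in the vector libraries (SD, n = 3 each; 57 to 108 reads per library; edgeR, adjusted p = 0.00148). A C16orf13 exon (chromosome 16, 684889 to 684956) had 62.4% ± 5.21 against 94.0% ± 1.74 (adjusted p = 3.52e-07), and an ADAM15 exon (chromosome 1, 155034380 to 155034451) 25.4% ± 4.44 against 51.4% ± 5.75 (adjusted p = 0.00392). Exons of SLC2A8 (56.4% against 82.5%) and MMEL1 (65.1% against 91.4%) completed the 5 largest falls. The MMEL1 event had few reads in the libraries labelled KDM4B. Inclusion reads there were 16, 14 and 13 against 84, 102 and 88 in the vector libraries, and skipping reads 8, 8 and 7 against 5, 6 and 15. A BIN1 exon (chromosome 2, 127815049 to 127815177), from a tumour suppressor gene with known splice variants, had 37.8% ± 7.05 against 59.6% ± 2.17 (adjusted p = 0.0213).

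More inclusion was called for exons of EXOC7 (90.2% against 72.8%), FAM208B (95.6% against 78.5%), MYO6 (35.6% against 19.96%), PPFIA2 (22.3% against 9.23%) and ZZZ3 (99.5% against 89.6%). Few skipping reads lay behind 2 of these. ZZZ3 had 1, 0 and 0 in the libraries labelled KDM4B against 5, 8 and 12 in the vector libraries. FAM208B had 4, 3 and 0 against 15, 21 and 8. The EXOC7 exon lay at chromosome 17, 74087224 to 74087316, and was covered by 135 to 159 reads per library. Coordinates are as deposited, except that starts were shifted to count from 1. Only 12.5% of SE exons lay inside their gene on GRCh38, although the submitters' processing notes name that build. The build of these positions is therefore uncertain. Without vector replicate 1 the SE count dropped to 10 (0 higher), without vector replicate 2 it was 32 and without vector replicate 3 it was 20. Among the falls, the CPNE7 call was lost without vector replicate 1 (adjusted p = 0.0515), the ADAM15 call without vector replicate 3 (0.0675), the BIN1 call without vector replicate 1 or 3 (0.0988 and 0.0922) and the MMEL1 call without vector replicate 1 or 2 (0.0988 and 0.108). The SLC2A8 call was lost without KDM4B replicate 4 (0.0782) and without vector replicate 1, 2 or 3 (0.107, 0.0702 and 0.0928). All 5 named rises lost their call without at least 1 library: FAM208B without any of the 6 (adjusted p from 0.0565 to 0.175), MYO6 in all cases but KDM4B replicate 4 (0.0624 to 0.111), PPFIA2 in all but KDM4B replicate 1 (0.0607 to 0.138), ZZZ3 without KDM4B replicate 2 or any vector library (0.0502 to 0.0922) and EXOC7 without vector replicate 1 (0.0973). The C16orf13 fall was the only named SE call that held in all 6 cases, and with limma only C16orf13 and ZZZ3 were called (adjusted p = 0.0315 and 0.0451). With DESeq2 the calls of FAM208B, MYO6, PPFIA2 and BIN1 were lost (adjusted p = 0.0630, 0.0903, 0.0957 and 0.0740).

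Events deposited as mutually exclusive exons changed in both directions. In the libraries labelled KDM4B, the exon with the lower coordinates had a larger share of the pair's reads in 29 of 2997 tested MXE events and a smaller share in 20. These calls lay in 30 genes (limma called 12 larger and 2 smaller, DESeq2 7 and 3). Each test compares the reads of 2 exons. Whether transcripts hold only 1 of them was not tested, so a call does not show an exchange of exons. Shares are given for the exon with the lower coordinates, which on the minus strand is the later exon of the transcript. In a CTNND1 (p120 catenin) pair it took 29.5% ± 2.21 of reads against 16.0% ± 1.58 (SD, n = 3 each; adjusted p = 0.000138), in a MARK2 pair 60.5% ± 5.44 against 44.1% ± 3.78, and in a BIN1 pair, on the minus strand, 83.8% ± 5.16 against 70.9% ± 3.12. Pairs in SLC29A2, ALOX15 and GPR137 were the other large rises. The falls were led by pairs in WBSCR27 (25.7% against 47.7%), C16orf13 (46.3% against 63.1%), SDCCAG3 (10.3% against 27.0%), ACSL1 (12.0% against 22.5%) and DNM2 (76.5% against 86.8%). No KDM4B event could be tested. Over SE and MXE events together, 45 changed by at least 10 percentage points, 18 up and 27 down. Without vector replicate 1 the count was 19 (10 up and 9 down), without vector replicate 2 it was 27 (11 and 16), without vector replicate 3 it was 23 (10 and 13), and with limma it was 9 (6 and 3). The 45 events are not all independent. The C16orf13 SE exon is also the lower-coordinate exon of the C16orf13 MXE pair, with the same reads. The BIN1 SE exon is the other exon of the BIN1 MXE pair, and 2 CTNND1 events share 1 exon pair. A flank of the BIN1 SE event ends at 127808819, where the lower-coordinate exon of the BIN1 pair also ends. Its inclusion form thus joins both exons, so that pair is not exclusive as these events are defined. The SLC29A2 call was lost in every case of a left-out library but KDM4B replicate 2 (adjusted p from 0.0808 to 0.154), the GPR137 call without KDM4B replicate 1, vector replicate 1 or vector replicate 3 (0.171, 0.110 and 0.0801), the WBSCR27 call without KDM4B replicate 2 or vector replicate 1 (0.0640 and 0.0818), the ALOX15 call without KDM4B replicate 4 (0.0731) and the MARK2 call without vector replicate 1 (0.0553). Of the MXE pairs named here, only those in CTNND1 were called with limma (adjusted p = 0.0195), and only those in CTNND1 and SDCCAG3 with DESeq2 (SDCCAG3, adjusted p = 0.0438).

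**Figure D4:**
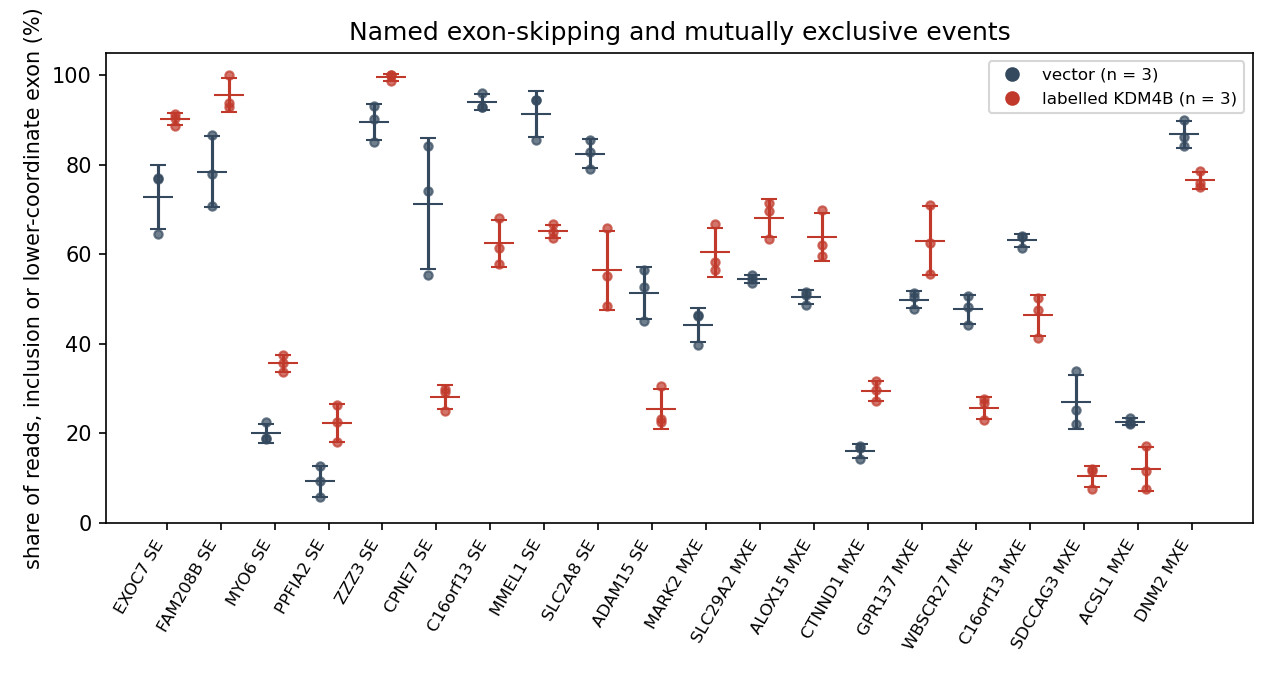
Share of reads, in percent, that belonged to the inclusion form (SE) or the exon with the lower coordinates (MXE) for 20 named events, with 1 point per library and the mean ± SD of 3 libraries, in vector libraries and libraries labelled KDM4B. The CPNE7 exon averages 28.0% in the libraries labelled KDM4B and 71.3% in the vector libraries.

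A5SS and RI events have a single count per library, so each was tested against the summed SE counts of its gene, and a call shows a change of the event relative to those exons, not of a splice form. Of 1193 A5SS events 22 rose and 22 fell, led by FXYD3 (26.5% against 13.0% of event plus SE counts) among the rises and EVA1B (55.4% against 75.7%) among the falls. Of 783 RI events 65 rose and 42 fell. The rises included introns of RANGRF (69.6% against 55.8%), ELP5 (55.9% against 42.2%), ATPIF1 (49.0% against 36.3%; adjusted p = 3.03e-06) and GTPBP2 (39.5% against 27.1%), and the falls EVA1B (42.1% against 74.3%), ATAD3B (56.2% against 74.9%) and LTN1 (24.8% against 40.8%; adjusted p = 4.90e-07). The FXYD3 call was lost without any single library but KDM4B replicate 4 (adjusted p from 0.0696 to 0.186), with limma (0.151) and with DESeq2 (0.152). The RANGRF call was lost without KDM4B replicate 2 or 4 (0.0688 and 0.0579), without vector replicate 1 or 3 (0.0776 and 0.0544), with limma (0.0519) and with DESeq2 (0.0566). The other A5SS and RI calls named here held in each of these settings. The EVA1B events of both types cover overlapping positions and were set against the same SE counts, so their calls are not independent. SE events of a gene share reads, so a read can enter the summed SE counts more than once. The A5SS count was 13 without KDM4B replicate 1 (6 up and 7 down), 20 without vector replicate 1 (8 and 12), 12 without vector replicate 2 (3 and 9) and 22 without vector replicate 3 (12 and 10). It was 11 with limma (2 and 9), 16 with DESeq2 (9 and 7) and 9 at an adjusted p below 0.01 (2 and 7), so the even split did not hold in every setting.

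An enrichment of genes changed in expression among genes with a changed SE or MXE event did not pass the test. Of 1851 genes tested for both, 1468 changed in expression, 61 in splicing and 50 in both (odds ratio 1.19, 95% interval 0.605 to 2.57; Fisher's exact test, two-sided p = 0.748). Expression calls here came from FPKM as deposited, which counted most genes as changed. The test therefore had little room to show an enrichment, and it does not show that there is none. The overlap was not tested with scaled expression calls. Without vector replicate 3 the odds ratio was 2.05. With expression changes of at least 2-fold, a choice made after seeing the data, it was 2.84 (Fisher's exact test, two-sided p = 0.0195), from 7 genes changed in both.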

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

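The tests in this part were chosen only after the results were seen, except that the median-of-ratios scaling was set before the data were examined. With 3 samples per group, no test for outlying samples was run, although vector replicate 1 stood apart from the other vector libraries in its ribosomal RNA.

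The first pattern is the fall of androgen-induced genes in the libraries labelled KDM4B. A shift of scale between the libraries is argued against, because the median log2 fold change of the list was still -1.14 after scaling, with quartiles of -1.84 and -0.64. At least 2-fold more KDM4B mRNA, as the table counts it, is argued against by a scaled log2 fold change of 0.31, with 0.38 at 2 SE above it; transgene reads that did not align would be missed. Mesenchymal cells are argued against by 5 of their abundant transcripts (VIM, COL1A1, COL1A2, SPARC and LGALS1), of which the highest, COL1A1, had 2.92 FPKM in these libraries, although FN1 rose to 33.2 FPKM. Cells of another epithelial type were not tested and stay open. Weaker androgen signalling, through the transgene or through the culture, would raise androgen-repressed genes, whose scaled median was 1.68, but transgene and culture cannot be told apart because each group had its own cells.

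The second pattern is the rise of RNAs without a poly(A) tail. More ribosomal RNA transcription alone is argued against by RNA polymerase III products outside the ribosome, of which the least changed, RN7SL1, had a scaled log2 fold change of 1.37. A difference in RNA selection or library making stays open. The 39 histone genes taken as replication-dependent, whose lack of a tail was not checked singly, stood above 8 histone variants by 0.36 (log2). A bootstrap over genes gave an interval of 0.136 to 0.976, which does not cover the spread between libraries. The difference lies in the direction that this explanation needs but short of the 1 set for it. A difference in biology between the groups was not tested.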

How the results depend on the processing

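The count test on SE events and the 2-fold overlap were chosen after seeing the data, and what the splits of the samples would show was written down after their outcome was seen. The binomial test on genes with SE calls was not planned. Total counts of changed and 2-fold changed genes, both directions together, stayed within 1.5 times under every other alternative run, with ranges of 8367 to 8894 and 549 to 574 when a library was left out. Counts by direction moved more. With a mean FPKM of at least 5, 74 genes were higher and 324 lower by 2-fold, against 152 and 416 in the main test. The edgeR test on the most-read SE event of each gene called 3918 of 8464 genes, 1962 higher and 1956 lower. That fit also normalizes the libraries, and median-of-ratios scaling likewise gave a near-even split (4136 higher and 4114 lower). The cause of the smaller number of calls was not tested. Camera with an estimated correlation called 0 lists (3 at an unadjusted p below 0.05) and fry, which does not compare a list with other genes, 20. For SE, MXE, A5SS and RI events, limma on the logit called 19, 14, 11 and 65 events and DESeq2 48, 10, 16 and 69; the cause was not tested. At an adjusted p below 0.01 the stricter threshold left 19 SE, 9 A5SS and 68 RI events. Leaving out a library gave 10 to 69 SE, 33 to 47 MXE, 12 to 45 A5SS and 72 to 117 RI events, 19 to 43 events changed by 10 percentage points, 10 to 12 lists and overlap odds ratios of 1.54 to 2.05; fewer samples were then tested. The count at 10 points was 19 without vector replicate 1, 27 without vector replicate 2 and 23 without vector replicate 3. It was 81 at 5 points, 12 at 20 points and 9 with limma. The overlap odds ratio was 2.84 with 2-fold expression calls. Signs turned for KDM4A (0.10 scaled, 0.10 quantile normalized, 0.033 in the count test), NFKBIA (0.12 scaled, 0.12 quantile normalized) and KDM4C (0.15 in the count test). The median log2 fold change of all tested genes was -0.22 as deposited, and scaling removed this shift, so small falls could turn. Why KDM4C turned only in the count test was not tested. Of 43 named events, 21 lost their call without vector replicate 1 and 28 with limma.

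Only 2 replicate numbers occur in both groups, and their libraries' deviations from the group means correlated at -0.024 and 0.13, so the numbers do not establish pairing. With the replicate block 8459 genes, 580 genes changed 2-fold and 11 lists were called. The same block in the limma fit called 0 SE, 0 MXE, 0 A5SS and 0 RI events (210, 188, 117 and 152 at an unadjusted p below 0.05) and 0 events changed by 10 points, with few residual degrees of freedom. The 10 splits of 3 against 3 are too few for a share under 0.05. All splits but the real split mix the groups, which puts the group difference into the spread within each side. Few calls in them were thus fixed in advance and lend no support to the calls of the real split. The real split, 1 of the 10, gave 8951 genes, 568 genes changed 2-fold, and 75 SE, 49 MXE, 44 A5SS and 107 RI events, and the highest of the other splits 0 in each case (58 genes and 57, 150, 60 and 29 events at an unadjusted p below 0.05). Simulated log2 odds ratios of 1 were recovered in 10.0% of cases for SE events, with a median of 93 reads per event in the lowest library, and in 72.0% for MXE events, with 187; no simulation separated depth from the spread between libraries.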

Other observations

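The genes in this part were chosen, and their tests set, only after their values were seen, except that the share among other genes near 0 was tested before it was seen. Several genes of the cleavage-stage embryo, a set switched on by the factor DUX4, were near 0 in the vector libraries and higher in the libraries labelled KDM4B. Of 49 such genes in the table, 27 were higher in all 3 libraries labelled KDM4B than in all 3 vector libraries and 3 were lower. This count only describes a list drawn up with its values in view. For a single gene, chance leaves the groups without overlap in 5% of cases in each direction. Among tested genes 76.3% had no overlap, but that share joins both directions and covers only genes with a mean FPKM of at least 1. It is therefore not a like baseline for this list. PRAMEF1 measured 1.81 to 2.38 FPKM against 0 to 0.09 FPKM, PRAMEF12 2.04 to 2.09 against 0.02 to 0.07 FPKM, TRIM43 1.14 to 1.38 against 0.03 to 0.08 FPKM, TRIM49 1.13 to 1.32 against 0.07 to 0.14 FPKM, MBD3L2 1.66 to 2.44 against 0 to 0.23 FPKM and ZSCAN4 0.25 to 0.55 against 0 to 0.02 FPKM. TRIM43B was listed at 0 in the 3 vector libraries and at 0.65 to 1.08 FPKM in the others. DUXA went the other way, at 2.25 to 2.44 against 5.79 to 7 FPKM, as did SLC2A3 and TRIM49D1, and DUX4 itself was listed at 0 in all libraries but KDM4B replicate 4 (0.17 FPKM).

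The third pattern weighed is this rise of cleavage-stage genes. Of 42 members with a vector mean below 0.1 FPKM, 21 (50%) had at least 0.1 FPKM in all 3 libraries labelled KDM4B, as did 247 of 4305 other such genes (5.74%). The bound set for this comparison presumed a list picked without its values; since picking alone could fill such a list, a general rise of genes near 0 stays open. Reads shared between copies of a gene family cannot be told apart from a rise of each gene, since 24 of the 27 belong to multi-copy families and the same list serves here; outside these families 3 of 12 members were higher. That the libraries labelled KDM4B hold a weak cleavage-stage programme is a hypothesis that these values leave open, and no test here ties it to the transgene.

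Other genes singled out after their values were seen were the BMP-responsive ID1 (15.9 against 2.58 FPKM), ID3 (41.8 against 7.52 FPKM) and SMAD6 (6.55 against 2.07 FPKM), which rose, and the small nucleolar RNA host genes SNHG1 (47.5 against 160 FPKM), SNHG12 (10.5 against 32.9 FPKM) and SNHG17 (10.8 against 34.8 FPKM), which fell (limma, adjusted p between 1.70e-09 and 6.71e-08 for all 6). Of the metallothionein genes, MT1X rose (33.8 against 22.7 FPKM; limma, adjusted p = 1.39e-05), and MT2A measured 115 against 106 FPKM (adjusted p = 0.0897 as deposited, 9.82e-05 after scaling).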
